A study of Mus musculus with 17 samples.

How the data were processed

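The study measured gene expression by RNA sequencing in brown adipose tissue (BAT), the fat depot that oxidises lipid to produce heat, from C57BL/6J mice. C57BL/6J is a common inbred laboratory strain. Samples came from wild-type mice and from mice in which the Acbp gene was deleted in brown adipocytes (Acbp BAd-KO, here also called the knockout). Acbp, annotated as Dbi, encodes acyl-CoA-binding protein, which binds long-chain acyl-CoA esters in the cytosol. Per the labels' protocols, mice were kept at 22 °C on a standard chow or were fed a high-fat diet (HFD, 45% of calories from fat) for 12 weeks. Total RNA was isolated with NucleoSpin columns and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. The driver line behind the deletion, the time of day of tissue collection and the age of the mice are not given in the sources used here.

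The authors deposited 1 table of unscaled whole-number counts per gene, with 55414 genes and 1 column for each of the 17 libraries. The labels name FastQC, STAR 2.7.8a, RSEM 1.3.0, DESeq and the genome build GRCm39, without saying what each was used for. RSEM shares ambiguous reads among genes, so the counts deposited by the authors may be rounded RSEM estimates. In that case genes with close paralogs carry an uncertainty that the counts do not show. The gene annotation, the strand setting and any filter are not given in the sources used here. All values were checked to be whole numbers, and 25996 genes had 0 counts in every library. Genes with the same symbol were kept apart by identifier, and 79 symbols occurred more than once.

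Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr, which left 17717 genes, of which 14386 were annotated as protein coding. Library totals were scaled by trimmed mean of M-values (TMM) factors. A quasi-likelihood negative binomial model was fitted to all 17 libraries with 1 coefficient per group. Each comparison was tested with the quasi-likelihood F test, two-sided, and p values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p of 0.05 or less. Fold changes are given on the log2 scale with a standard error (SE) derived from the fitted fold change and its F statistic. Expression levels are CPM, counts scaled to a common library total with the TMM factors, as mean ± standard deviation (SD) over libraries. Before the data were examined, the comparisons, the gene lists, the rule for naming genes and the first set of alternative settings were chosen. The comparisons were genotype on chow, genotype on HFD, diet in wild-type, diet in the knockout, the genotype by diet interaction and the genotype effect averaged over diets.

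The rule for naming genes took Dbi first, then Ucp1, Dio2, Ppargc1a, Cidea, Elovl3, Fgf21 and Lep whatever their test. It added the 8 called genes with the largest rise and the 8 with the largest drop that had a mean of at least 1 CPM in the higher group and a symbol that was not a predicted gene or clone name. Of the genes this rule took, 2 are not reported here. Up to 4 members of each described list with the smallest adjusted p were named, and so were the genes of the checks on sex, on substrain and on the neighbours of Dbi and Ucp1. A set of 47 gene lists was tested with camera and fry from limma 3.58.1. Camera compares a list with all other genes and was run with a preset inter-gene correlation of 0.01 and again with an estimated correlation. The PValue of fry asks whether the genes of a list move, on balance, in 1 direction. Its PValue.Mixed asks whether they change in either direction, and neither compares the list with other genes. Adjusted p values for lists are over the 47 lists. The lists included skeletal muscle markers as a sign of RNA from muscle. A further list of 33 hepatocyte transcripts was added after liver transcripts were seen in some libraries, so it is no independent evidence.

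Depth ranged from 39.6 to 105 megacounts per library, so replicate spread and not counting error limits the values of all but the weakest genes. The pipeline was tested on simulated data in which 67, 67 and 66 of the 17717 genes were changed by 1.5, 2 and 4-fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of weaker genes was not measured. Counts were drawn independently for each gene, without variation shared between genes, such as that from muscle or liver RNA. The real libraries may therefore give more false calls than the simulated ones. For genotype on chow it recovered 43.3%, 82.1% and 95.5% of these, with 6 false calls. For genotype on HFD it recovered 50.7%, 86.6% and 95.5%, with 9 false calls. For diet in wild-type it recovered 41.8%, 80.6% and 93.9%, with 7 false calls. For the interaction it recovered 22.4%, 58.2% and 87.9%, with 6 false calls, and for the averaged genotype effect 77.6%, 95.5% and 100%, with 9 false calls.

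Alternatives chosen at the start were DESeq2 1.42.0, limma-voom, size factors by relative log expression (RLE), no filter, a filter at a mean of 1 CPM, an adjusted p threshold of 0.1, fits on the compared groups alone and leaving out each library in turn. Others were a block for the replicate number, a term for the run of library numbers on HFD, and leaving out the 2 chow wild-type libraries whose library numbers lie apart. After the data had been seen, covariates for muscle and liver RNA, fits without libraries rich in either, and scaling by library totals alone were added. Left out as muscle-rich were HFD wild-type 1 and HFD knockout 2, 4 and 5. Left out as liver-rich were HFD wild-type 5 and HFD knockout 4 and 5. No chow library was left out, although chow wild-type 1 and 3 and chow knockout 4 held 3079, 3302 and 1927 CPM of muscle markers. Comparisons of a single measure between groups used exact two-sided permutation tests. A reference annotation was used only for gene names and neighbour order. It belongs to the older build GRCm38, not to GRCm39, and so no coordinates are given. No sample was left out of the main model, and reads were not analysed here.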

Results

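Transcript levels were measured in BAT from wild-type and Acbp BAd-KO mice on chow or HFD, a design that asks what loss of acyl-CoA-binding protein in brown adipocytes does to the tissue and whether diet matters. There were 4 chow wild-type, 3 chow knockout, 5 HFD wild-type and 5 HFD knockout samples, each with its own library. The labels do not say that the samples are separate animals, so the p values measure the spread between these samples. Library totals in megacounts (M) were 39.6 to 43.9 M in chow wild-type, 47.2 to 49.7 M in chow knockout, 60 to 105 M in HFD wild-type and 60.2 to 101 M in HFD knockout. Library numbers of the 2 diets did not overlap, so diet and any difference between library runs cannot be separated.

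Transcripts of skeletal muscle and of hepatocytes were present in unequal amounts, and how they came into the libraries was not tested. Skeletal muscle markers, such as the actin gene Acta1 and the myosin gene Myh4, summed to 8720 CPM in HFD wild-type 1 and to 42.4 to 61.3 CPM in the other 4 HFD wild-type libraries. In HFD knockout, libraries 2, 4 and 5 held 14400, 3370 and 3380 CPM, and libraries 1 and 3 held 51.6 and 79.7 CPM. Chow wild-type libraries held 543 to 3302 CPM and chow knockout libraries 36.2 to 1927 CPM. Transcripts of the hepatocyte list summed to 17.8 ± 1.06 CPM in chow wild-type and 76.7 ± 47.3 CPM in chow knockout (SD, n = 4 and 3). Albumin (Alb) alone stood at 0.294 ± 0.367 CPM in chow wild-type and 15.9 ± 19.3 CPM in chow knockout. The chow wild-type sum thus came mostly from other members of the list, and whether liver RNA gave it was not tested. The sum reached 363 CPM in HFD wild-type 5 and 343 and 476 CPM in HFD knockout 4 and 5, out of a range of 6.39 to 476 CPM on HFD. Among 24 comparisons of library measures, the hepatocyte sum differed between genotypes on chow at an exact permutation p of 0.0286, the smallest possible there, with an adjusted p of 0.0763. The library total had the same p values on chow, with means of 48.07 M in the knockout and 41.88 M in wild-type, so genotype and depth go together there. The mean log2 level of the muscle list did not differ between genotypes on HFD beyond replicate spread (exact permutation p = 0.365, adjusted p = 0.515).

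**Figure D1:**
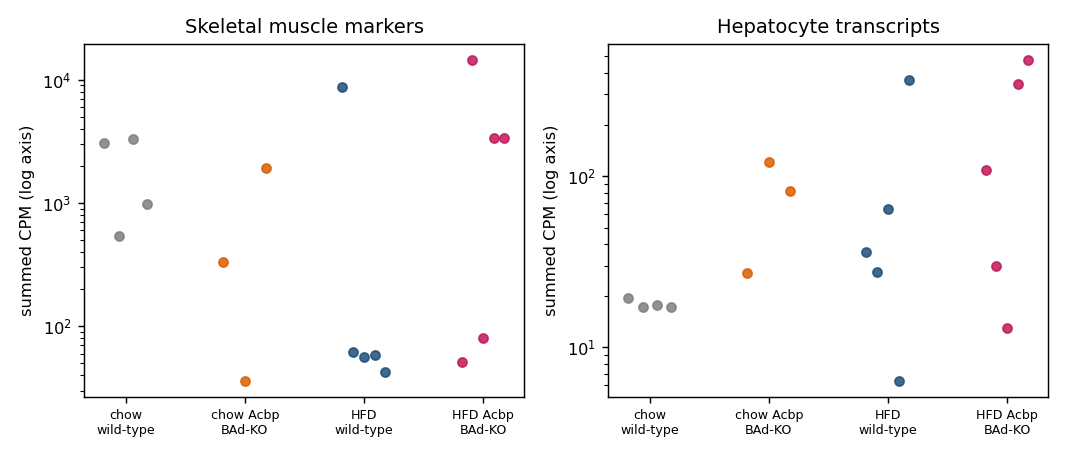
Summed CPM of 26 skeletal muscle markers and of 33 hepatocyte transcripts in each of the 17 libraries, on a log axis, with 1 point per library and libraries grouped by genotype and diet. Chow wild-type 1 and 3, chow knockout 4, HFD wild-type 1 and HFD knockout 2, 4 and 5 lie above 1000 CPM of muscle markers, and HFD wild-type 5 and HFD knockout 4 and 5 lie at 343 to 476 CPM of hepatocyte transcripts.

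Dbi (ENSMUSG00000026385.17), the targeted gene on chromosome 1, was lower in every knockout library than in every wild-type library on the same diet. On chow its level was 97.2 ± 7.93 CPM in the knockout (SD, n = 3) and 1020 ± 64.6 CPM in wild-type (n = 4), a log2 fold change of -3.39 ± 0.13 (SE, adjusted p = 2.68e-10) that left 9.51% of the wild-type level. On HFD it was 128 ± 21.3 CPM in the knockout and 701 ± 55.6 CPM in wild-type (n = 5 each), a log2 fold change of -2.45 ± 0.10 (adjusted p = 6.39e-10) that left 18.3%. Per library, 8.64% to 10.1% of the wild-type mean remained on chow and 15.8% to 23.5% on HFD. In wild-type mice Dbi fell 1.46-fold on HFD (log2 fold change -0.54 ± 0.10, adjusted p = 0.000846), but under scaling by library totals the change was -0.08 and not called. The reduction by genotype passed under all alternatives tried, with adjusted p up to 0.00176 on chow and 0.0258 on HFD.

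**Figure D2:**
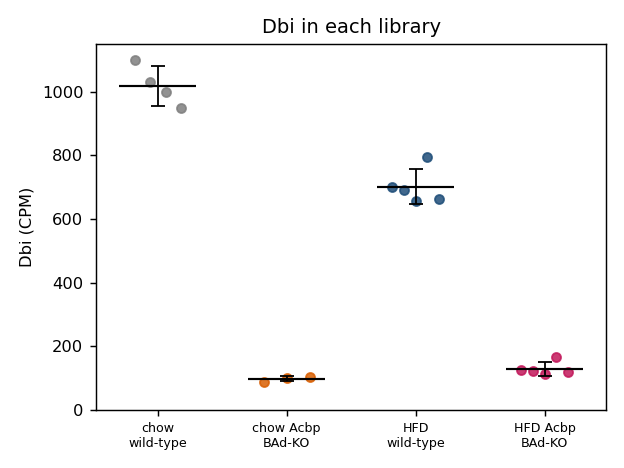
Dbi in CPM after TMM scaling for each of the 17 libraries, grouped by genotype and diet, with 1 point per library and bars for mean ± SD. Knockout libraries span 88.3 to 103 CPM on chow and 111 to 165 CPM on HFD, and wild-type libraries span 949 to 1100 CPM on chow and 658 to 795 CPM on HFD.

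On chow, Dio2, Ppargc1a and Nr4a3 rose in the knockout and Lep fell. Dio2, the deiodinase that raises active thyroid hormone inside brown adipocytes, rose 3.79-fold, from 93.8 ± 48.4 to 355 ± 37.4 CPM (log2 fold change 1.92 ± 0.44, adjusted p = 0.0458, n = 4 and 3). Ppargc1a, a coactivator of mitochondrial biogenesis, rose 3.01-fold, from 58.7 ± 10.6 to 177 ± 48.6 CPM (1.59 ± 0.29, adjusted p = 0.0161). Nr4a3, a nuclear receptor gene induced by cAMP, rose 6.28-fold, from 6.49 ± 2.35 to 40.7 ± 8.2 CPM (2.65 ± 0.39, adjusted p = 0.00534). Lep, which encodes leptin, fell 9.46-fold, from 45.1 ± 21.2 to 4.77 ± 3.16 CPM (-3.24 ± 0.69, adjusted p = 0.035).

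Ucp1, the uncoupling protein that makes brown fat produce heat, stood at 3100 ± 76.5 CPM in the knockout and 2290 ± 726 CPM in wild-type on chow and was not called (0.44 ± 0.25, adjusted p = 0.437). The lipid droplet gene Cidea (-0.08 ± 0.14), the fatty acid elongase gene Elovl3 (-0.53 ± 0.33) and the hormone gene Fgf21 (-0.61 ± 0.46) were not called either. Tbc1d9 rose 3.35-fold (1.74 ± 0.13, adjusted p = 4.27e-06) and its neighbour across Ucp1, Elmod2, rose 2.82-fold (1.49 ± 0.13, adjusted p = 2.02e-05). Among the largest other changes, Gldn, which encodes gliomedin, fell 3.84-fold (-1.94 ± 0.30, adjusted p = 0.00796). The small nuclear RNA gene Rnu1a1 (-1.78 ± 0.32), Gprin3 (-1.54 ± 0.26), BC049352 (-1.61 ± 0.32), Sox9 (-1.50 ± 0.34) and Lzts1 (-1.47 ± 0.29) fell too. Serpina1e, a protease inhibitor gene of the liver, rose from 0.0489 ± 0.0464 to 2.39 ± 1.93 CPM, beside the higher hepatocyte sum of the chow knockout libraries. Lrrc52 (3.08 ± 0.69), Ccno (2.33 ± 0.54) and Cldn1 (1.99 ± 0.46) rose at adjusted p values of 0.043 to 0.0478.

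The β-adrenergic and cAMP signalling list had 2 of 22 tested members up and 0 down on chow, and 7 up and 1 down when adjusted over the list alone. Nr4a3 and the cAMP phosphodiesterase gene Pde4d (0.83 ± 0.13, adjusted p = 0.00929) were the called members, and Crem (0.51 ± 0.12, adjusted p = 0.0538) was not called. Camera called the list higher (adjusted p = 0.0287), with adjusted p = 0.968 with an estimated correlation. The thermogenic list had 2 of 25 up, Dio2 and Ppargc1a, and 2 up when adjusted over the list alone (camera adjusted p = 0.157). Of 18 circadian clock genes, the repressor genes Cry2 (-0.88 ± 0.14, adjusted p = 0.00796) and Bhlhe41 (-1.34 ± 0.23, adjusted p = 0.0136) fell. Adjusted over the list alone, 3 clock genes rose and 6 fell, and fry's PValue.Mixed was 0.000189 after adjustment, although its PValue was 0.131 and camera's 0.107. Endocrine factors of brown fat had 1 of 19 up (Nrg4, 0.47 ± 0.09) and 2 down (S100b, -0.70 ± 0.15, and Lep), or 2 up and 4 down when adjusted over the list alone. This was the 1 list fry called by direction on chow (adjusted p = 0.00941); the median of its log2 fold changes was -0.05, and 0.02 under scaling by library totals.

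Cytosolic ribosomal protein genes lay higher in the chow knockout in 48 of 49 cases, by a median log2 fold change of 0.14, with 0 called up or down over all genes and 0 when adjusted over the list alone (edgeR). Camera called them higher (adjusted p = 9.94e-08), with adjusted p = 0.968 with an estimated correlation. Immediate early genes, which answer quickly to stimuli, lay lower by a median of -0.51, with 0 of 22 called and 3 down when adjusted over the list alone. Camera called them lower (adjusted p = 0.00511), again with adjusted p = 0.968 with an estimated correlation. All 26 muscle markers were lower on chow, by a median of -1.25, and 0 were called over all genes or over the list alone; camera gave an adjusted p of 0.00511, and 0.968 as the adjusted p with an estimated correlation. All 33 hepatocyte transcripts were higher in the chow knockout and 1 was called. No list kept its camera call with an estimated correlation in any comparison. The number of lists with an unadjusted p under 0.05 there was 0 for chow, 8 for HFD, 4 for diet in wild-type and 1 for the interaction.

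In all, 92 genes rose and 95 fell on chow among 17717 tested, 24 and 42 of them by at least 2-fold. An unadjusted p under 0.05 was found for 2692 genes against 886 by chance. The groups of 186 called genes did not overlap, as for 12.8% of all genes tested, where chance gives 5.71%. Scaling by library totals gave 83 up and 48 down. The chow count fell to 75 without wild-type 2, 106 without knockout 2, 28 without knockout 3 and 23 without knockout 4, to 16 without wild-type 1 and 2, and to 29 with muscle and liver scores in the model. The liver score is the log2 of the hepatocyte sum, which was 17.12 to 19.38 CPM in chow wild-type and 27.02 to 121.1 CPM in chow knockout libraries. These ranges do not overlap, so the score may remove genotype effects on chow too, and the fall to 29 cannot be assigned to liver RNA.

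Without single libraries some chow calls ended. Dio2 was no longer called without wild-type 1, 2 or 4 (adjusted p = 0.106, 0.0735 and 0.0807) or without knockout 2, 3 or 4 (0.0771, 0.129 and 0.145), and its log2 fold change stayed between 1.71 and 2.19. Ppargc1a was not called without wild-type 2 (adjusted p = 0.053) or knockout 2 or 3 (0.0579 and 0.081). Lep was not called without wild-type 1, 2 or 4 (0.0748, 0.0667 and 0.0523) or knockout 3 or 4 (0.16 and 0.154). With muscle and liver scores in the model Dio2 (1.59 ± 0.43, adjusted p = 0.18), Ppargc1a (1.28 ± 0.27, 0.0769) and Lep (-3.06 ± 0.68, 0.0946) were not called, and with limma-voom Dio2 (0.0517) and Lep (0.162) were not. Over all alternatives the adjusted p ran from 0.00493 to 0.207 for Dio2, from 0.000158 to 0.165 for Lep, and up to 0.148 for Ppargc1a and 0.101 for Nr4a3, and each upper end came without wild-type 1 and 2 together. The calls of Serpina1e, Lrrc52, Ccno, Cldn1, Sox9, Lzts1, Rnu1a1, Gprin3 and BC049352 all ended without knockout 3 (adjusted p = 0.0601 to 0.184) and without knockout 4 (0.0689 to 0.208) and those of the first 6 also without wild-type 1 (0.0554 to 0.114). Of these 9, some ended without wild-type 2 (Serpina1e, Ccno, Cldn1, Sox9 and Lzts1), wild-type 3 (Serpina1e, Lrrc52 and Ccno), wild-type 4 (Serpina1e, Lrrc52, Ccno and Cldn1) or knockout 2 (Lrrc52, Ccno, BC049352 and Sox9). Dbi, Nr4a3, Tbc1d9, Gldn and Elmod2 passed without each library in turn.

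**Figure D3:**
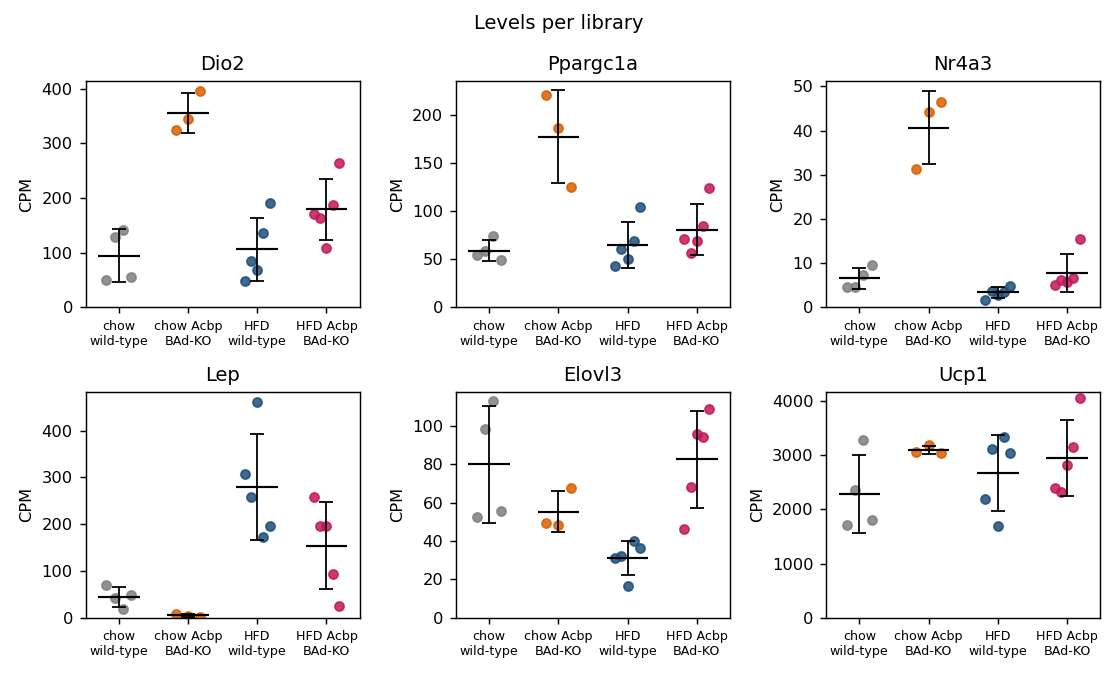
CPM after TMM scaling of Dio2, Ppargc1a, Nr4a3, Lep, Elovl3 and Ucp1 in the 4 groups, with 1 point per library and bars for mean ± SD (n = 4, 3, 5 and 5). On chow the knockout libraries of Dio2 lie at 325 to 397 CPM and those of wild-type at 48.7 to 142 CPM, whereas on HFD the 2 genotypes overlap.

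On HFD, Scd1, Insig1, Elovl3 and Stip1 rose in the knockout. Scd1, the desaturase that makes monounsaturated fatty acids, rose 1.86-fold, from 38000 ± 4540 to 70700 ± 11700 CPM (log2 fold change 0.90 ± 0.14, adjusted p = 0.0095, n = 5 each). Insig1, a sterol-responsive gene that restrains lipid synthesis, rose 1.83-fold, from 192 ± 21.3 to 351 ± 35.0 CPM (0.87 ± 0.09, adjusted p = 0.000418). Elovl3 rose 2.64-fold, from 31.3 ± 8.80 to 82.6 ± 25.1 CPM (1.40 ± 0.27, adjusted p = 0.0337). Stip1, which encodes a co-chaperone of heat shock proteins, rose 1.77-fold, from 51.4 ± 7.33 to 91.2 ± 17.1 CPM (0.83 ± 0.12, adjusted p = 0.00684).

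Gsta3, a glutathione transferase gene, rose 3.09-fold (1.63 ± 0.29, adjusted p = 0.0218) on HFD, and Rims2 (1.90 ± 0.41), Col6a6 (1.48 ± 0.30) and Tmem184a (0.93 ± 0.20) rose at adjusted p values of 0.0428 to 0.0491. Tbc1d9 rose 1.77-fold (0.82 ± 0.11, adjusted p = 0.00274) and Elmod2 1.61-fold (0.69 ± 0.11, adjusted p = 0.0095). Eya2 (-1.51 ± 0.23) and Tram2 (-1.31 ± 0.19) fell at adjusted p values of 0.00531 to 0.0095. Wwc1 (-1.46 ± 0.32), Nrxn2 (-1.23 ± 0.26), Rorb (-1.14 ± 0.20) and Gldn (-1.10 ± 0.23) fell at 0.0204 to 0.0491. Dio2 stood at 179 ± 56.2 CPM in the HFD knockout and 105 ± 57.5 CPM in wild-type and was not called (0.77 ± 0.36, adjusted p = 0.391). Ppargc1a (0.31 ± 0.24), Lep (-0.86 ± 0.50), Ucp1 (0.14 ± 0.21), Cidea (0.19 ± 0.12), Fgf21 (-0.41 ± 0.32) and Nr4a3 (1.23 ± 0.33) were not called on HFD. Ppargc1a turned to -0.03 and Ucp1 to -0.11 without the 4 muscle-rich HFD libraries, and Ucp1 to -0.04 without the 3 liver-rich ones and -0.16 with the run of library numbers in the model.

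Among heat shock genes 2 of 14 rose on HFD, Hsp90ab1 (0.59 ± 0.10, adjusted p = 0.0129) and Dnaja1 (0.79 ± 0.17, adjusted p = 0.0481), and 10 rose and 0 fell when adjusted over the list alone. The list lay higher by a median log2 fold change of 0.77 (camera adjusted p = 2.86e-12, fry 0.0107), and by 0.56 without the 4 muscle-rich libraries. Its adjusted p was 0.253 with an estimated correlation. The mean log2 level of this list increased with library number within HFD wild-type, from 5.76 to 6.76, and was 6.81 to 7.31 in the knockout libraries, so genotype and library order cannot be told apart for it. Of 23 genes of cholesterol synthesis, Insig1, Cyp51 (0.46 ± 0.09) and Sqle (0.64 ± 0.13) rose and Hmgcs1 (-0.34 ± 0.07) fell, and 10 rose and 1 fell when adjusted over the list alone. That list had a median of 0.27, a camera adjusted p of 1.34e-06 and a fry adjusted p of 0.0419, with adjusted p = 0.261 with an estimated correlation. De novo lipogenesis had 1 of 19 up (Scd1) and 8 up when adjusted over the list alone, with a median of 0.37 (camera adjusted p = 1.16e-07, fry 0.0922). Its adjusted p was 0.355 with an estimated correlation. The list of acyl-CoA binding, synthesis and hydrolysis had 3 of 26 up, Acsf2 (0.49 ± 0.09), Fabp5 (0.67 ± 0.13) and Acsl3 (0.75 ± 0.16), and 4 up when adjusted over the list alone. Camera gave that list an adjusted p of 2.19e-06 and fry 0.0419, with adjusted p = 0.253 with an estimated correlation.

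All 37 genes of respiratory complex I lay higher in the HFD knockout, by a median of 0.22, with 0 called over all genes and 5 up when adjusted over the list alone. Camera gave an adjusted p of 2.86e-12, but the adjusted p was 0.544 with an estimated correlation. Without the 4 muscle-rich libraries the median was 0.03 (camera adjusted p = 0.0581). The muscle list had a median of 1.14, with 21 of 26 markers higher and 0 called over all genes or over the list alone (camera adjusted p = 8.88e-05). Its adjusted p was 0.706 with an estimated correlation. The hepatocyte list had 32 of 33 transcripts higher and 0 called. Immediate early genes had 0 of 22 called on HFD and 1 up and 9 down when adjusted over the list alone, with a median of -0.51 (camera adjusted p = 9.13e-07, fry 0.0419). Their adjusted p was 0.253 with an estimated correlation. Endothelial markers had 1 of 20 down (Emcn, -0.40 ± 0.08) and 7 down when adjusted over the list alone, with a median of -0.21 (camera adjusted p = 7.62e-07). Their adjusted p was 0.261 with an estimated correlation, and without the 4 muscle-rich libraries the median was -0.10.

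In all, 55 genes rose and 40 fell on HFD, 8 and 11 of them by at least 2-fold, with 2256 at an unadjusted p under 0.05. The groups of 87 called genes did not overlap, as for 3.6% of all genes, where chance gives 0.794%. Scaling by library totals shifted the median of all genes by -0.147 and gave 33 up and 388 down. The HFD count moved with single libraries, to 30, 26, 37 and 56 without wild-type 1, 2, 3 and 4, to 207 without wild-type 5, to 149 without knockout 1, and to 35, 50, 20 and 41 without knockout 2, 3, 4 and 5. It was 5 without the 4 muscle-rich HFD libraries, 19 without the 3 liver-rich ones and 16 with muscle and liver scores in the model. Without the muscle-rich libraries only knockout 1 and 3 remain on HFD, so fewer samples alone may lower the count. With the run of library numbers in the model it was 1, where only 1 knockout library shares the run of wild-type. That model was fitted to the HFD libraries alone, and the same fit without the run term called 17.

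Elovl3 on HFD was not called without wild-type 1, 2 or 3 (adjusted p = 0.0856, 0.0875 and 0.0653) or without knockout 2, 3, 4 or 5 (0.0502, 0.0685, 0.106 and 0.0821), and its log2 fold change stayed between 1.24 and 1.55. Gsta3 was not called without wild-type 1 or 2 or knockout 2 or 4 (0.0563, 0.0537, 0.0502 and 0.0796), nor was Rorb without wild-type 2 (0.0613) or knockout 2 or 4. The calls of Rims2, Col6a6, Tmem184a, Wwc1, Nrxn2 and Gldn ended without 6 to 9 of the 10 HFD libraries, in all 6 cases without knockout 4 (0.129 to 0.148). Without the 4 muscle-rich libraries Dbi, Insig1 and Scd1 passed, and the other named calls ended, with Elovl3 at 1.17, Stip1 at 0.72, Tbc1d9 at 0.74 and Eya2 at -1.12. Without the 3 liver-rich libraries Elovl3 (1.22, adjusted p = 0.202), Eya2 (0.125) and Elmod2 (0.116) were among those not called. With only the 2 HFD groups in the fit, Elovl3 (0.0688), Scd1 (0.0767), Stip1 (0.0591), Gsta3 (0.0688) and Tram2 (0.0591) were not called. With the run of library numbers added to that fit only Dbi passed. Insig1 (0.78, adjusted p = 1), Scd1 (1.07, 1) and Elovl3 (0.57, 1) did not, nor did Stip1, which stood at 0.56. Apart from that model, Insig1 passed under all alternatives.

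In the 9 genes called by genotype on both diets, the direction was the same on each: 5 were higher in the knockout, where 0.286 would be called both times by chance, and 4 lower, against 0.214. They were Dbi, Gldn, Mmp28 and Zfp518b, which fell, and Tbc1d9, Elmod2, Gsta3, Anp32e and the autophagy receptor gene Sqstm1, which rose. The rule did not cover Mmp28, Zfp518b, Anp32e and Sqstm1, which were chosen after their values were seen. Sqstm1 rose by 0.52 ± 0.11 on chow and 0.46 ± 0.09 on HFD. Averaged over diets, 233 genes rose and 273 fell, or 60 and 212 under scaling by library totals. This count of 506 was 133 without chow knockout 3, 163 without chow knockout 4 and 276 to 313 without chow wild-type 1 or 2, HFD wild-type 1 or 2 or HFD knockout 4. It was 107 without chow wild-type 1 and 2 together, 34 with muscle and liver scores in the model, 23 without the 4 muscle-rich HFD libraries and 322 without the 3 liver-rich ones. Over all genes the log2 fold changes by genotype on chow and HFD correlated weakly across genes, which are not independent replicates (Pearson r = 0.191, permutation p = 0.11; Spearman rho = 0.139, permutation p = 0.16; one-sided, 100 permutations). Without HFD wild-type 1 the r was -0.076, without the 4 muscle-rich HFD libraries -0.032, and without HFD wild-type 5 0.382.

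**Figure D4:**
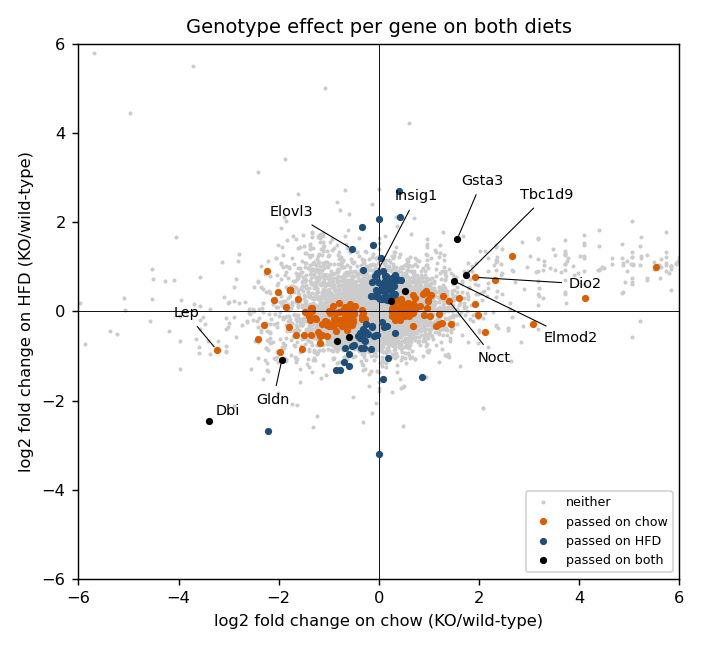
Log2 fold change by genotype on chow (x axis) and on HFD (y axis) for each tested gene, with genes called on chow, on HFD, on both or on neither in different colours; 46 genes lie outside the axes, which end at 6 on the log2 scale. The 9 genes called on both diets lie in the quadrants of equal sign, and Dbi is lowest among them at -3.39 and -2.45.

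In the GRCm38 annotation, Tbc1d9 and Elmod2 are the genes directly before and after Ucp1 on chromosome 8. In the fit averaged over diets they ranked 2 and 3 by p after Dbi, with log2 fold changes of 1.28 ± 0.09 and 1.09 ± 0.09 (adjusted p = 5.57e-07 and 3.74e-06). None of the 14 tested genes at 2 to 10 places from Ucp1 was called by edgeR there; 3 had an unadjusted p under 0.05 and DESeq2 called 1. On HFD the call of Elmod2 ended with muscle and liver scores in the model (0.67 ± 0.12, adjusted p = 0.0509), and with the run of library numbers (0.81, 0.22), in a range of 5.84e-07 to 0.59 over alternatives.

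**Figure D5:**
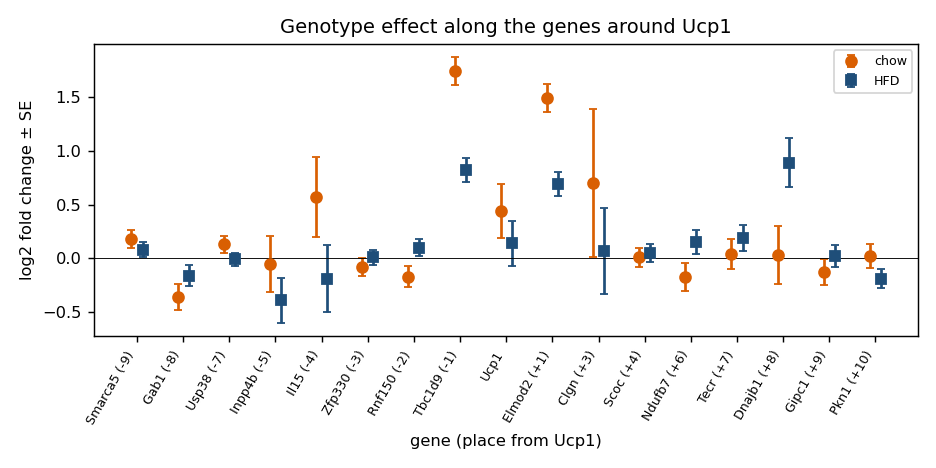
Log2 fold change by genotype (points, ± SE) on chow and on HFD for Ucp1 and the tested genes up to 10 places to either side, in the gene order of the GRCm38 annotation. Tbc1d9 (1.74 and 0.82) and Elmod2 (1.49 and 0.69) stand above their neighbours, and Ucp1 itself (0.44 and 0.14) was not called.

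The interaction asks whether the genotype effect differs between diets. Dbi was reduced less on HFD than on chow, by 0.94 ± 0.15 on the log2 scale (adjusted p = 0.0377). Insig1 rose with genotype on HFD and stood at -0.04 ± 0.11 on chow, a difference of 0.91 ± 0.15 (adjusted p = 0.0377). Noct, a rhythmically expressed gene, rose 2.63-fold with genotype on chow and stood at 0.24 ± 0.12 on HFD, a difference of -1.15 ± 0.19 (adjusted p = 0.0388). Socs2, a suppressor of cytokine signalling, rose on chow (1.2 ± 0.17) and stood at -0.29 ± 0.14 on HFD, a difference of -1.50 ± 0.22.

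Gulp1 (-1.46 ± 0.24), Sh3pxd2a (-1 ± 0.15), the amino acid transporter subunit gene Slc3a2 (-0.93 ± 0.16), Cmtm6 (-0.63 ± 0.09), Sav1 (-0.62 ± 0.11) and Lrrc8d (-0.49 ± 0.08) had a lower genotype effect on HFD than on chow. Rnu1a1 had a higher one (2.25 ± 0.40). For 4 genes called on chow the difference between diets was not called: Dio2 -1.16 ± 0.56 (adjusted p = 0.495), Ppargc1a -1.28 ± 0.38 (0.229), Nr4a3 -1.42 ± 0.50 (0.326) and Lep 2.38 ± 0.81 (0.308). Elovl3 (1.93 ± 0.43, adjusted p = 0.0931), Tbc1d9 (-0.92 ± 0.17, 0.0527) and Elmod2 (-0.81 ± 0.17, 0.0844) were just short of it, and Ucp1 (-0.30 ± 0.33), Cidea (0.27 ± 0.19) and Fgf21 (0.20 ± 0.56) were not called. Of 18 circadian clock genes 0 were called over all genes, and 8 had a higher and 2 a lower genotype effect on HFD when adjusted over the list alone, among them Bhlhe41 (1.41 ± 0.29) and Cry2 (0.72 ± 0.17). Camera called the list (adjusted p = 0.000989) and fry as well (0.039), with adjusted p = 0.23 with an estimated correlation. All 26 muscle markers had a higher genotype effect on HFD than on chow, by a median of 2.59.

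In all, 8 genes had a higher and 8 a lower genotype effect on HFD, with 1837 at an unadjusted p under 0.05. Scaling by library totals shifted the median by -0.211 and gave 7 and 56. Each of the named calls ended without several single libraries. All of them also ended with the muscle score in the model, with muscle and liver scores, and without the 4 muscle-rich HFD libraries. In these 3 settings edgeR called 0 genes, and 1450, 1417 and 1270 had an unadjusted p under 0.05. The count was 0 by edgeR without chow wild-type 2, chow knockout 2, chow knockout 4, HFD wild-type 2 or HFD knockout 2, where 1631, 1791, 1636, 1792 and 1583 genes had an unadjusted p under 0.05. It was 6 without chow wild-type 1 and without HFD wild-type 1, 1 without chow knockout 3 or HFD knockout 4, and 33 without HFD knockout 5. DESeq2 called 196 genes on all libraries and limma-voom 10.

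In wild-type mice, Lep and Gdf15 rose on HFD and Scd3, Elovl3 and Cidea fell. Lep rose 6.2-fold, from 45.1 ± 21.2 to 279 ± 114 CPM (2.63 ± 0.57, adjusted p = 0.00256, n = 4 and 5). Scd3, a desaturase gene, fell 14.1-fold (-3.81 ± 0.25, adjusted p = 1.1e-07). The stress hormone gene Gdf15 rose 86.9-fold (6.44 ± 0.86, adjusted p = 5.43e-05), a change that was not followed under the other settings. Elovl3 fell 2.55-fold (-1.35 ± 0.28, adjusted p = 0.00193) and Cidea 1.53-fold (-0.61 ± 0.12, adjusted p = 0.00159), although under scaling by library totals Cidea was not called (-0.16).

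Fgf21 rose in the wild-type mice from 0.366 ± 0.191 to 1.02 ± 0.245 CPM (1.47 ± 0.38, adjusted p = 0.0072), and Tbc1d9 rose 2.12-fold (1.09 ± 0.12). Ucp1 (0.23 ± 0.22), Dio2 (0.17 ± 0.38) and Ppargc1a (0.15 ± 0.26) were not called, and Dio2 and Ppargc1a changed sign under other settings. Elmod2 fell 1.28-fold (-0.35 ± 0.12, adjusted p = 0.0277), but it lay higher under scaling by library totals (0.14). The other largest drops were those of Phyhip (-4.72 ± 0.35), the xenobiotic enzyme gene Cyp1a1 (-4.45 ± 0.35), Tjp3 (-3.51 ± 0.35), Orm3 (-2.82 ± 0.24) and the presynaptic gene Bsn (-2.81 ± 0.33). H2ac19 fell from 2.66 to 6.71 CPM in the chow libraries to 0 counts in 4 of the 5 HFD libraries and 0.702 CPM in HFD wild-type 3, so no fold is given; its adjusted p was 0.0227, but 0.23 with DESeq2 and 0.115 without chow wild-type 1 and 2. The 8 largest rises were all in liver transcripts, Mug1, Cps1, Ttr, Bhmt, Fgg, Mup19, Plg and Mup20, whose HFD wild-type means were 1.11 to 3.36 CPM. Apart from Mup20 they had 0 counts in every chow wild-type library, so no fold is given. Their level was highest in HFD wild-type 5 (4.19 to 14.4 CPM), the library with a hepatocyte sum of 363 CPM, and 28 of the 33 hepatocyte transcripts were called higher.

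Of 19 genes of de novo lipogenesis, 17 fell on HFD and 0 rose, and 18 fell and 1 rose when adjusted over the list alone; examples are Elovl5 (-1.64 ± 0.13), the acetyl-CoA synthetase gene Acss2 (-1.54 ± 0.16) and the carboxylase gene Acacb (-1.36 ± 0.14). Cholesterol synthesis had 17 of 23 down and 1 up, and 19 down and 1 up when adjusted over the list alone, with Sqle (-1.85 ± 0.14), Insig1 (-1.69 ± 0.10) and Cyp51 (-1.28 ± 0.10). Camera gave adjusted p values of 3.5e-10 and 1.35e-10 for these lists, and 0.436 was the adjusted p with an estimated correlation for both. Under scaling by library totals 12 fell in each list, and 1 and 3 rose. Complex I had 28 of 37 genes down and 0 up, and 32 down when adjusted over the list alone, for example Ndufa1 (-0.92 ± 0.11) and Ndufa5 (-0.90 ± 0.11), with a median of -0.48 (camera adjusted p = 1.61e-12). Its adjusted p was 0.44 with an estimated correlation, and under scaling by library totals only 9 fell, 5 rose and the median was -0.02. Complexes II to V had 24 of 39 down, such as Cox6c (-1.03 ± 0.09), and 24 when adjusted over the list alone. Their median was -0.38 (camera adjusted p = 4.1e-09), which flipped to 0.08 under scaling by library totals. Their adjusted p was 0.549 with an estimated correlation. Mitochondrial transcripts took 23.1% of counts in HFD wild-type and 28.95% in chow wild-type libraries (exact permutation p = 0.00794, adjusted p = 0.0614).

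Macrophage markers rose on HFD in 20 of 25 cases and 0 fell, with 20 up when adjusted over the list alone, for example Lgals3 (3.31 ± 0.47, 9.91-fold), Gpnmb (3.68 ± 0.57, 12.8-fold) and Adgre1 (1.52 ± 0.27, 2.87-fold). Cell cycle genes rose in 19 of 25 cases and 21 when adjusted over the list alone, with Cdk1 (2.37 ± 0.36) and Top2a (2.34 ± 0.36). Camera gave adjusted p values of 6.31e-08 and 4.11e-08, and 0.44 was the adjusted p with an estimated correlation for both. Fibroblast and matrix genes had 20 of 31 up and 1 down, and 24 up and 1 down when adjusted over the list alone, with Sparc (0.86 ± 0.12) and Bgn (1.12 ± 0.19) up and Postn (-0.46 ± 0.08) down. Camera gave an adjusted p of 2.45e-05, and the adjusted p was 0.579 with an estimated correlation. White adipocyte markers had 8 of 13 up and 1 down, and 9 up and 1 down when adjusted over the list alone, including Npr3 (2.41 ± 0.24) and Mest (4.15 ± 0.74); the camera adjusted p was 0.00459 and the adjusted p with an estimated correlation 0.549. The integrated stress and unfolded protein response list had 15 of 28 up and 3 down, and 16 up and 4 down when adjusted over the list alone, with Atf3 (1.83 ± 0.20) and Phgdh (2.47 ± 0.35) besides Gdf15. Camera gave an adjusted p of 0.00128, and the adjusted p was 0.436 with an estimated correlation. Under scaling by library totals the medians of these 5 lists were 0.71 to 1.81. That scaling raised the median of all genes by 0.476, so it could hardly have turned a rise and is no check on these lists.

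In all, 2986 genes rose and 2699 fell with diet in wild-type mice, with 7515 at an unadjusted p under 0.05 and non-overlapping groups in 4038 called genes (24.8% of all genes, where chance gives 1.59%). In the knockout 2260 rose and 2319 fell, and 3065 genes were called in both genotypes, 1571 up and 1476 down in both against 381 and 353 expected of independent lists. The β-adrenergic and cAMP list fell in 11 of 22 members in the knockout (11 down and 1 up when adjusted over the list alone), for example Nr4a3 (-2.38 ± 0.36); camera gave an adjusted p of 0.000944, and the adjusted p was 0.511 with an estimated correlation. Under scaling by library totals 8 members fell and 4 rose. Scaling by library totals shifted the median of all genes by 0.476 in wild-type and 0.265 in the knockout, and gave 10497 up and 426 down and 5322 up and 553 down, so directions are relative to the bulk of genes. The calls of the 8 liver transcripts ended without HFD wild-type 5 (adjusted p = 0.057 to 0.132), with limma-voom (0.412 to 0.569) and mostly also without single chow wild-type libraries. That of Elmod2 ended without chow wild-type 4 (0.118) or HFD wild-type 1, 4 or 5 (0.0505, 0.0527 and 0.0562), in a range of 0.0113 to 0.347 over alternatives.

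The genotype effect on HFD and the diet effect in wild-type share the 5 HFD wild-type libraries. Of the 95 genes called by genotype on HFD, 68 were also called by diet in wild-type: 33 were higher in the knockout and lower on HFD, against 8.38 expected of independent lists, and 31 the reverse, against 6.74. Examples are Insig1, Scd1 and Elovl3, which fell with HFD in wild-type mice and were higher in the HFD knockout. Across genes the 2 sets of log2 fold changes had r = -0.108 and a covariance of -0.0377, and counts simulated without any effect gave a mean r of -0.433 and a covariance of -0.0652 from the shared libraries alone. With separate HFD wild-type libraries for the 2 comparisons, the median over 20 draws was r = 0.134 (-0.269 to 0.371) and a covariance of 0.0772. Of genes called in both there were 1 to 203 (median 10.5), and 0 to 186 had opposite signs (median 8.5). For chow genotype and diet in wild-type, which share the 4 chow wild-type libraries, r was 0.465 with a covariance of 0.326, and simulation gave 0.505 and 0.103.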

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

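Of the tests below, those on the extra copy, liver RNA and time of day were chosen after the results were seen. The models with muscle and liver scores or the Dio2 level were chosen after the data had been seen but before their own results. The library number run and leaving out chow wild-type 1 and 2 were chosen at the start as other settings and read as tests of these patterns only after the results were seen, and the others were chosen before. A value counted as far from the rest of its group when its gap to the nearest other sample was a larger share of the group's range than Dixon's 95% limit. Of 172 groups tested, 27 had such a value, where chance gives about 1 in 20, or 8.6. Groups of 3 were not tested.

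On HFD, Dbi stood at 165 CPM in knockout 4 against 111 to 126 CPM in the other 4 knockout libraries, still far below the wild-type. Nr4a3 stood at 15.5 CPM in HFD knockout 5 against 4.98 to 6.47 CPM, and Insig1 at 413 CPM in HFD knockout 3 against 329 to 345 CPM. In HFD wild-type 3, Tmem184a was at 0.388 CPM against 0.635 to 0.714, Sav1 at 48.6 against 41.3 to 43.1, and H2ac19 at 0.702 against 0. In HFD wild-type 2 Rims2 was at 0.5 CPM against 0.251 to 0.276, and in HFD wild-type 1 Phyhip was at 0.252 against 0.0817 to 0.115. In chow wild-type 3, Cldn1 was at 4.48 CPM against 1.62 to 1.75, Lzts1 at 1.45 against 3.26 to 3.38, and Cyp1a1 at 2.67 against 1.47 to 1.57. In chow wild-type 4, Scd1 was at 102000 CPM against 75900 to 77600, and Stip1 at 59 against 51.1 to 51.7.

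HFD wild-type 5 stood apart in Mug1 (10.4 CPM), Cps1 (7.86), Ttr (7.41), Bhmt (5.43), Fgg (4.9), Mup19 (4.71), Plg (4.19), Mup20 (14.4) and the hepatocyte sum (363 CPM against 6.39 to 64.5), so these 9 values come from 1 library. Scd3 was at 0.286 CPM there, against 0.175 to 0.204. Mup20 was at 0.0274 CPM in chow wild-type 2 and 0 in the other chow wild-type libraries. The muscle sum was 8720 CPM in HFD wild-type 1 against 42.4 to 61.3 CPM, and 14400 CPM in HFD knockout 2 against 51.6 to 3380 CPM. The total of HFD knockout 5 was 101 megacounts against 60.2 to 67.7.

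The genotype effect differed between diets by the interaction test in 11 named genes. The differences in log2 fold change were 0.94 for Dbi, 2.25 for Rnu1a1, 0.91 for Insig1, -1.5 for Socs2, -1.46 for Gulp1, -1.15 for Noct, -1 for Sh3pxd2a, -0.93 for Slc3a2, -0.63 for Cmtm6, -0.62 for Sav1 and -0.49 for Lrrc8d. None of the 11 kept its call without each library in turn. Of 100 splits of the samples 5 gave at least the real 16 genes, the highest other 221, so chance is not excluded for this count. What the split with 221 genes separates was not tested.

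Tbc1d9 and Elmod2, directly beside Ucp1, were higher in the knockout on both diets. Muscle and liver RNA as the whole cause is argued against, since with both scores in the model the lower of the averaged log2 fold changes was 1.07. With the Dio2 level in the model the averaged log2 fold changes were 1.02 ± 0.12 for Tbc1d9 and 1.19 ± 0.15 for Elmod2, both still called. What the Dio2 level tracks is thus argued against as the whole cause. On HFD the call of Elmod2 ended in that model (0.74 ± 0.13, adjusted p = 0.0518). Of the 187 chow calls only Dbi, Tbc1d9 and Elmod2 then passed. Dio2 is 1 transcript and itself follows genotype on chow, so thermogenic activation that it does not mark was not tested. A candidate explanation that stays open is RNA from an extra copy of the region around Ucp1, such as a transgene carrying its neighbours: 0 of 14 tested genes at 2 to 10 places away passed by edgeR in the averaged fit (3 at an unadjusted p under 0.05, 1 by DESeq2). This count was set after the pattern had been seen and largely restates it. Ucp1 itself, between the 2 genes, was not called (0.44 ± 0.25 on chow and 0.14 ± 0.21 on HFD). Tbc1d9 and Elmod2 rose by 1.74 and 1.49 on chow and by 0.82 and 0.69 on HFD, differences that were not called. The driver line is not given in the sources used here, and a local effect of genotype on the region was not tested.

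Genes called by genotype on HFD mostly lay opposite to the diet effect in wild-type. With separate HFD wild-type libraries for the 2 comparisons the median correlation was 0.134, not negative, so the negative correlation across genes may come from the shared libraries; over the 20 draws 1 to 203 genes were called in both and 0 to 186 were opposite (medians 10.5 and 8.5), so whether the opposite signs outlast the sharing stays open. With the muscle score in the model 33 of 37 genes called in both were opposite (89.2%), just short of the 90% set for excluding muscle RNA. That fit still shares the HFD wild-type libraries, which alone favour opposite signs, so neither outcome could have excluded muscle RNA. With separate libraries and the muscle score the median r was 0.085 (-0.395 to 0.414). The median number of genes called in both was then 5.5, with 4 opposite, so muscle RNA cannot be told apart. In a fit to the HFD libraries alone, 1 gene passed with the library number run in the model and 17 without it. Since 1 knockout library shares the run of wild-type, run and genotype cannot be told apart. An opposing effect of genotype on the response to diet stays open as well.

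Dio2, Ppargc1a, Nr4a3 and Noct rose in the chow knockout; the rule named Noct for the interaction only, and its chow value was chosen after it was seen. Liver RNA as their direct source is argued against, because Alb gained 15.6 CPM and the 4 genes gained 262, 118, 34.2 and 89.4 CPM. Yet with muscle and liver scores in the model the log2 fold changes were 1.59 ± 0.43, 1.28 ± 0.27, 2.33 ± 0.38 and 1.25 ± 0.15. The calls of Dio2 and Ppargc1a ended in that model (adjusted p = 0.18 and 0.0769). The liver score does not overlap between genotypes on chow, so that model may remove genotype effects as well. Early library numbers as the whole cause are argued against too: without chow wild-type 1 and 2 the log2 fold changes were 1.84 ± 0.54, 1.53 ± 0.40, 2.28 ± 0.49 and 1.3 ± 0.19, the lowest 1.3. The calls of the first 3 ended there (adjusted p = 0.207, 0.148 and 0.101) with larger errors from fewer samples. Another time of day at collection stays open, and so does an effect of genotype on thermogenic activation. Of 18 clock genes 9 changed when adjusted over the list alone, as many or more in 0.03% of 10000 random lists matched on expression (random median 1). The random lists were not matched on variation that clock genes may share between libraries, so this share may be too small.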

How the results depend on the processing

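Models with muscle or liver scores, fits without muscle-rich or liver-rich libraries and scaling by library totals were chosen after seeing the data. Dbi by genotype kept its direction and its call throughout. Of 2044 values of 87 named results under alternatives, 1512 kept direction and side of the threshold (74%), 503 lost the call, 11 gained it and 18 reversed. The cause was not tested for the changes below, beyond fewer samples or genes by construction.

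Gene counts are given for chow, HFD, the interaction and the average over diets (187, 95, 16 and 506). They were 473, 266, 63 and 1011 at an adjusted p of 0.1, 608, 588, 196 and 1117 with DESeq2, and 81, 192, 10 and 250 with limma-voom. Without a filter chow gave 122, HFD 57 and the average 331, and with the stricter filter the interaction gave 25. Without chow wild-type 1 and 2, chow gave 16, the interaction 1 and the average 107. With the muscle score chow gave 105, HFD 54 and the interaction 0. With muscle and liver scores the 4 counts were 29, 16, 0 and 34. The liver score does not overlap between genotypes on chow, so it may remove genotype effects there too. Without the 4 muscle-rich libraries HFD gave 5, the interaction 0 and the average 23, and without the 3 liver-rich ones HFD gave 19 and the average 322. With library totals HFD gave 421, the interaction 63, the average 272 and diet in wild-type 10923 instead of 5685. HFD gave 17 with only its 2 groups, and 1 with the library number run added to that fit. Leaving out each library gave 23 to 185 on chow, 20 to 207 on HFD, 0 to 33 for the interaction, 133 to 699 for the average, 4734 to 5642 for diet in wild-type and 3166 to 4397 for diet in the knockout. For the counts of 0 by edgeR, 1450, 1417 and 1270 genes had an unadjusted p under 0.05 with the muscle score, with both scores and without muscle-rich libraries.

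Replicate numbers did not clearly pair the samples: the correlation of same-numbered samples was -0.72 to 0.22 over the 4 comparisons. For diet in the knockout the 3 correlations were 0.07 to 0.22 and 2 samples matched their own number best, so pairing is not excluded there. A block for the replicate number gave 10 genes on chow, 23 on HFD, 0 for the interaction (edgeR; 1760 at an unadjusted p under 0.05, and 196 by DESeq2 without block), 266 averaged, 2503 by diet in wild-type and 2998 in the knockout, and 7 lists on chow. With the block Ppargc1a (-0.09) and Dio2 (-0.12) turned negative for diet in wild-type, and the interaction of Fgf21 was 0.

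Camera's lists numbered 4 on chow, 26 on HFD, 21 by diet in wild-type and 17 for the interaction. They were 0 in all 4 with an estimated correlation (0, 8, 4 and 1 at an unadjusted p under 0.05), and fry called 1 on chow, 7 on HFD and 1 for the interaction. HFD had 13 lists without muscle-rich libraries, 14 without liver-rich ones and 17 with library totals, where diet in wild-type had 12, and the interaction had 10 without muscle-rich libraries. Leaving out each library gave 2 to 7 on chow, 12 to 27 on HFD, 19 to 26 by diet and 14 to 22 for the interaction.

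The correlation between diets turned to -0.032 without muscle-rich libraries and ran from -0.076 (without HFD wild-type 1) to 0.382 (without HFD wild-type 5). By genotype on HFD, without muscle-rich libraries, Ppargc1a was -0.03 and Ucp1 -0.11, and Ucp1 was -0.04 without liver-rich ones and -0.16 with the library number run. For diet in wild-type Ppargc1a was -0.16 with both scores, -0.09 without liver-rich libraries and -0.09 to 0.27 without each library. Dio2 was -0.15, -0.16 and -0.16 to 0.44 in the same settings, and Elmod2 0.14 with library totals. The interaction of Fgf21 was -0.06 with limma-voom and ran from -0.09 to 0.56 without each library. Of these named results only Elmod2 had been called. Depth limits little here, and replicate spread limits the counts.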

Other observations

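The model with the Dio2 level was chosen after the data had been seen, though before its result, and the splits of samples were planned. Loss of Dbi on chow also went with higher Socs2 (1.2 ± 0.17, adjusted p = 0.0042) and Slc3a2 (1.28 ± 0.12, adjusted p = 4.55e-05), an amino acid transporter subunit gene, in 4 wild-type and 3 knockout samples. Noct rose 2.63-fold there, from 54.9 ± 7.41 to 144 ± 9.70 CPM (adjusted p = 0.000222). The rule named Socs2, Slc3a2 and Noct for the interaction only, and their chow values were chosen after they were seen. The chow calls of Socs2 and Slc3a2 were not followed under the other settings. In the knockout, HFD raised Lep 32.3-fold (5.02 ± 0.74, adjusted p = 0.000209), and Insig1 (-0.78 ± 0.11), Scd3 (-3.56 ± 0.25), Cyp1a1 (-5.13 ± 0.38) and Elmod2 (-1.16 ± 0.12) fell. Macrophage markers rose in 15 of 25 cases and 1 fell, and cholesterol synthesis fell in 16 of 23, with 18 up and 1 down, and 18 down, when adjusted over each list alone. Camera gave adjusted p values of 3.39e-05 and 1.6e-06, with adjusted p = 0.644 and 0.511 with an estimated correlation.

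Among the neighbours of Dbi in the GRCm38 order, Sctr, the secretin receptor gene 2 places away, was higher in the averaged fit (0.59, adjusted p = 0.0119) and was not called on chow (0.65 ± 0.16, adjusted p = 0.0645) or HFD (0.53 ± 0.13, adjusted p = 0.0866). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were expressed in all groups, with Ddx3y at means of 66.1 to 92.0 CPM, and Xist had group means of 0.0593 to 0.311 CPM. None of these differed between genotypes by edgeR's adjusted p on chow (Xist 0.207, Ddx3y 0.311) or HFD (0.873 and 0.286). The genes used to check the substrain, Wdfy1 (-0.25 ± 0.32 on chow), Entpd4 (0.09 ± 0.33) and the 2 genes named Nnt (-0.42 ± 0.75 and -0.34 ± 0.73), were not called by genotype on either diet.

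With the Dio2 level in the model, the genotype calls on chow numbered 3 instead of 187, on HFD 8 instead of 95 and averaged over diets 4 instead of 506. Dio2 itself follows genotype on chow, so this removes genotype effects along with those of Dio2.

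Other splits of the samples into groups of the same sizes were compared with the real ones. Only the real split reached the 187 genes by genotype on chow (1 of 35 splits, highest other 38) and the 5685 by diet in wild-type (1 of 100, 4058). The same held for the 4579 by diet in the knockout (1 of 56, 755) and the 506 averaged over diets (1 of 100, 2). Chance is thus unlikely for these counts. Each share is the smallest that its number of splits allows, and none was adjusted for the several results compared. For the 95 genes by genotype on HFD chance is not excluded, as 6 of 100 splits reached it and the highest other gave 304. The 4 splits with 260 to 304 genes were those with the largest differences in the muscle score, 5.41 to 6.17 against 2.65 for the real split, so they part muscle-rich from muscle-poor libraries; another split with 173 genes had a difference of 1.39. Chance is not excluded for the correlation of 0.191 between diets either (11 of 100; 0.487), nor for the numbers of lists called by camera: 4 on chow (25 of 35; 15), 26 on HFD (17 of 100; 31), 21 by diet in wild-type (30 of 100; 31) and 17 for the interaction (15 of 100; 24).

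No 2 replicates were copies of each other: in 29 pairs the Pearson r was 0.9494 to 0.9908, and chi-square per gene between replicates was 25.5 to 194, where counting error alone gives about 1.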
